A study of Mus musculus with 12 samples.

How the data were processed

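Gene expression was measured with Affymetrix mouse arrays in HM1 and CAG150 embryonic stem cells at day 4 and day 6 of neuronal differentiation, with 3 arrays in each of the 4 groups. The groups were taken from the sample titles. The sample descriptions give the earlier day for HM1 at day 6 and the same replicate number for every day 6 sample, and the titles were used. The labels give no array date, batch, culture or passage. Nothing says whether the samples of a group were separate cultures, and there was 1 line of each kind.

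The deposited values are intensities on a linear scale, scaled by the authors so that the mean over an array without the top and bottom 2% of probe sets is 150. This was read from the values themselves, since the software that made the intensity values is not given in the sources used here. No value per sample other than the intensity was deposited in the table used. The raw array files were not used here.

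The table has 45101 probe sets, of which 64 are controls and were left out. By the platform annotation given with the table, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none here, which does not mean that they have no gene. Only probe sets with 1 symbol were given a gene name, which covers 18193 genes. The symbols were matched by Entrez identifier to a gene table of the assembly GRCm38.p6, which changed 0 symbols and was otherwise used for chromosome names and the order of genes.

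Intensities were transformed as log2(intensity + 16). For each gene the probe set with the highest mean over all arrays was used, and genes were kept where this mean was above the 40th percentile of all probe sets, at 4.8 on the log2 scale or an intensity of 11.9. This left 12280 genes. No further normalization was made, since the log2 medians of the arrays differed by at most 0.25 and the upper quartiles by at most 0.19.

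A linear model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, so that all comparisons share an estimate of the spread (8 residual and 4.46 prior degrees of freedom, moderated with eBayes). From it came 6 comparisons: CAG150 minus HM1 at day 4, at day 6 and averaged over both days, day 6 minus day 4 in HM1 and in CAG150, and the difference between these day differences, the interaction. P-values were adjusted with the Benjamini-Hochberg method over all genes in each comparison, and a gene passed at an adjusted p under 0.05. The precision depends on the number of arrays. On simulated data with the real spread and independent genes, 47 of 100 genes changed by 0.5 on the log2 scale and 96 of 100 genes changed by 1 were found at day 4, with 5 false calls among the unchanged genes. At day 6 they were 51, 88 and 12. Far more genes passed in these comparisons of the real data, which moves the cutoff of the adjusted p, so these rates do not carry over directly.

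Gene lists of cell types, pathways and the line's identity, 29 in all, were tested with limma's camera with a preset correlation between genes of 0.01, and also with the correlation estimated from the data. P-values were adjusted over the lists in each comparison. Only members with a named probe set and enough signal were tested, and counts are given out of these. Some lists were cut strongly, such as Hox genes (7 of 24 tested), mesoderm (9 of 20), endoderm (12 of 20) and fibroblast and smooth muscle (9 of 16). Some lists share genes, such as the REST target and postmitotic neuron lists or the neuronal subtype and mesoderm lists, so their results are not independent. The rotation test fry was run as an alternative. Its p-value tests whether the genes of a list move on balance in 1 direction, and its mixed p-value whether they change in either direction. Neither compares the list with other genes. In the interaction 8 lists passed with the preset correlation and 0 with the estimated correlation.

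The text names Htt and Hprt, Tubb3, Pou5f1, Nes and Pax6 in any comparison. It also names the 8 largest rises and the 8 largest falls among genes that passed and whose groups did not overlap, which was asked of both days for the average and not asked for the interaction. From each list it may name up to 4 members with the largest fold change among those that passed, or the 1 with the smallest p, given as values, where none passed, and genes named in a comparison may be given in the others. The lists, this rule, the tests and the alternatives were set before the data were examined. Chosen after the data were seen were the tests by chromosome the fit without genes of chromosomes 8, 11 and Y, and the tests named as such in the closing observations.

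The shift of each chromosome was set against 10000 random gene sets of the same size, matched on mean signal. Overlaps of called genes were compared with the number given by independent lists. The alternatives were quantile normalization, median centring, no filter and a filter at the 60th percentile, pseudocounts of 1 and 64, other ways to choose among probe sets, only the arrays compared in the fit, a trended and robust prior, array weights, the replicate number as a block, stricter thresholds, and leaving out each array. The replicate numbers do not pair the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.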

Results

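Gene expression was measured in mouse HM1 and CAG150 embryonic stem cells at day 4 and day 6 of neuronal differentiation, on 12 Affymetrix arrays with 1 sample each. HM1 is a male mouse embryonic stem cell line that lacks a working Hprt gene. The CAG150 cells, per the series title, have expanded CAG repeats, which in this study lie in Htt, the Huntington's disease gene, as far as the study is known. Each of the 4 groups, a line at a day, had 3 samples. Each array gave the intensity of 45101 probe sets, 64 of them controls, and 12280 genes with a named probe set and enough signal were tested. Median intensities ranged from 19.2 to 25.9 between arrays. The number of arrays limits the precision of every value.

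Below, group values are mean intensities ± SD of 3 arrays. Differences are of log2(intensity + 16) ± SE, and folds are taken from these differences. All folds depend on the pseudocount of 16, the more so the dimmer a group is, and the fold of a dim gene is no bound. Values with other pseudocounts are given only where a group mean lay below the filter intensity of 11.9. P-values of genes are limma's, adjusted over the 12280 genes. A gene list's p is from limma's camera test with a preset correlation between genes, which compares the list with all other genes, and is adjusted over the 29 lists. With the correlation estimated instead, the p was often larger by many orders of magnitude. That p is given too where it missed 0.05, and for some lists that kept their call. The samples of a group are not described as separate cultures and there was 1 line of each kind, so all p-values measure only the spread between these samples.

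The first question was how CAG150 cells differed from HM1 cells early in differentiation. At day 4, CAG150 cells had less of the pluripotency genes. The lists of fibroblast and smooth muscle genes, lower, and of forebrain and midbrain genes, higher, passed with the preset correlation but each had adjusted p = 0.15 with an estimated correlation. Pou5f1, which keeps stem cells undifferentiated, fell from 341 ± 124 in HM1 to 105 ± 21 in CAG150 (log2 difference -1.52 ± 0.23, n = 3 per group, adjusted p = 0.00072). Tagln, an actin-binding protein of smooth muscle, fell 17.5-fold, from 1380 ± 58.9 to 63.9 ± 5.85 (-4.13 ± 0.12, adjusted p = 1.8e-09). En2, a midbrain and hindbrain regulator, rose 3.59-fold, from 25.4 ± 8.57 to 132 ± 27 (1.84 ± 0.16, adjusted p = 1e-05).

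Of the genes tested, 1940 (15.8%) passed at day 4, 967 higher and 973 lower in CAG150. Chromosomes 8 and 11 held 150 and 216 of the higher genes. Without chromosomes 8, 11 and Y, a fit added after the data were seen, 570 were higher and 876 lower. With the arrays centred on their medians instead, 534 were higher and 1165 lower. With the mean of a gene's probe sets, 1010 were higher and 762 lower. A difference of at least 2-fold was seen for 45 higher and 173 lower genes. The groups did not overlap for 4225 of all genes, where chance gives 10%, and for 1923 of those that passed. The largest rises were of Apcdd1, an inhibitor of Wnt signalling (181 ± 66 to 711 ± 118, 3.79-fold), En2, Wnt1 (3.31-fold), Rspo2, an activator of Wnt signalling (3.13-fold), Mab21l2 (2.98-fold), Rbfox3, the neuronal antigen NeuN (50.8 ± 21.3 to 178 ± 27.8, 2.98-fold), Pax3 (2.93-fold) and Gsx1 (4.1 ± 2.33 to 42 ± 8.24, 2.88-fold, or log2 differences of 3.17 and 0.64 with pseudocounts of 1 and 64). After Tagln, the largest falls were of Fgfbp1 (280 ± 13.4 to 12.6 ± 3.1, 10.4-fold), the Y-linked Eif2s3y (331 ± 20.2 to 19 ± 5.75, 9.99-fold), Cdkn1c, an imprinted inhibitor of the cell cycle (806 ± 63.1 to 113 ± 14.8, 6.39-fold), Egr2 (6.32-fold), Vgll3 (2520 ± 101 to 393 ± 78.7, 6.28-fold), Acta1 (6.17-fold) and Sema3e (6.14-fold).

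Among the neural lists at day 4, the neural progenitor list was higher in CAG150: 8 of its 20 tested genes rose and 0 fell, against 9 and 3 adjusted over the list alone (median log2 difference 0.19, adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation). Hes5, an effector of Notch that keeps progenitors dividing, rose from 639 ± 91.1 to 1780 ± 270, and Zic1 rose 1.98-fold. Of the 18 proneural and neurogenic genes 7 rose and 0 fell, against 9 and 0 adjusted over the list alone (median 0.29, adjusted p = 0.00072, and adjusted p = 0.15 with an estimated correlation). Neurog1 rose 2.07-fold and Nhlh2 1.96-fold. Of the 9 forebrain and midbrain genes 6 rose and 1 fell, against 7 and 1 adjusted over the list alone (median 1.15, adjusted p = 0.00072, and adjusted p = 0.15 with an estimated correlation). Otx1 rose 2.38-fold and Otx2, which specifies forebrain and midbrain, rose from 332 ± 20.1 to 782 ± 71.9. The member that fell was Lhx2, a forebrain regulator, with a log2 difference of -1.12, so the forebrain genes did not all move alike. The postmitotic neuron list did not pass as a group (8 of 30 higher, 4 lower, 10 and 5 adjusted over the list alone, median 0.15, adjusted p = 0.067). Its members went both ways: Stmn2, a microtubule regulator of growing axons, fell 3.42-fold, Mapk10 fell 2.41-fold and Gng3 fell 2.1-fold, while Rbfox3 rose. Tubb3, the neuronal tubulin, was 530 ± 47.7 in HM1 and 604 ± 79 in CAG150 (adjusted p = 0.41), Nes was 168 ± 35.6 and 124 ± 12.7 (adjusted p = 0.078), and Pax6 was 283 ± 8.65 and 328 ± 30.2 (adjusted p = 0.16).

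The pluripotency list fell at day 4: 11 of 18 genes were lower and 0 higher, against 13 and 0 adjusted over the list alone (median -0.75, adjusted p = 2.9e-10, and adjusted p = 0.0023 with an estimated correlation). Utf1 fell 3.77-fold and Dppa5a 3.49-fold. Of the 12 tested primitive and visceral endoderm genes 5 fell and 0 rose, against 6 and 0 adjusted over the list alone (median -0.41, adjusted p = 0.00057, and adjusted p = 0.061 with an estimated correlation). The list was fixed with 20 genes, and Afp, Ttr, Apoa1, Apob, Sox7, Amn and Apoc2 lay below the filter and were not tested. Sparc fell from 1420 ± 78.1 to 477 ± 27.4. Another of its probe sets had a log2 difference of 0.32. Apoe fell 2.62-fold. Of the 9 fibroblast and smooth muscle genes 4 fell and 0 rose, the same counts as adjusted over the list alone (median -0.24, adjusted p = 0.0011, and adjusted p = 0.15 with an estimated correlation). Acta2, smooth muscle actin, fell 6.11-fold.

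Some stress and metabolic lists were also lower in CAG150 at day 4 with the preset correlation, and none of these passed with an estimated one. Of 21 glycolysis and hypoxia genes 11 fell and 0 rose, against 14 and 0 adjusted over the list alone (median -0.43, adjusted p = 1.5e-06, and adjusted p = 0.15 with an estimated correlation). Ldha, lactate dehydrogenase, fell from 6590 ± 887 to 3430 ± 512 and Aldoa fell 1.92-fold. Of 16 p53 target and apoptosis genes 6 fell and 0 rose, against 7 and 0 adjusted over the list alone (median -0.17, adjusted p = 0.0012, and adjusted p = 0.061 with an estimated correlation). Perp fell 2.09-fold and Cdkn1a, an inhibitor of the cell cycle, fell 1.51-fold. Of 17 heat shock genes 5 fell and 0 rose, the same counts as adjusted over the list alone (median -0.13, adjusted p = 0.0033, and adjusted p = 0.22 with an estimated correlation). Hspb1 fell from 368 ± 16.8 to 59 ± 9.46. Of 20 imprinted genes 2 rose and 6 fell, the same counts as adjusted over the list alone (median -0.01, adjusted p = 0.047, and adjusted p = 0.22 with an estimated correlation). Grb10, a brake on insulin signalling, fell 4.63-fold. The list of Hprt and sex chromosome genes fell (2 of 4 lower, 0 higher, also adjusted over the list alone, median -1.22, adjusted p = 0.00089, and adjusted p = 0.061 with an estimated correlation).

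Other lists did not pass camera's test against all other genes at day 4. These were neuronal subtype identity (3 higher and 1 lower of 15, adjusted p = 0.69), retinoid response (5 and 2 of 14, adjusted p = 0.27), ventral neural tube (0 and 3 of 7, adjusted p = 0.061), neural crest (4 and 3 of 12, adjusted p = 0.71), mesoderm (0 and 3 of 9, adjusted p = 0.15), blood and endothelium (0 and 2 of 5, adjusted p = 0.12), Notch pathway (4 and 3 of 18, adjusted p = 0.13) and Wnt targets (2 and 0 of 10, adjusted p = 0.13). Also in this set were endoplasmic reticulum stress (1 and 4 of 19, adjusted p = 0.07), proteasome (2 and 2 of 31, adjusted p = 0.35), cholesterol synthesis (0 and 3 of 19, adjusted p = 0.077), REST targets and Bdnf (2 and 4 of 21, adjusted p = 0.69) and huntingtin and partners (1 and 1 of 11, adjusted p = 0.73). No gene passed among 6 glial (adjusted p = 0.73), 7 Hox (adjusted p = 0.73), 23 proliferation (adjusted p = 0.29) and 33 respiratory chain genes (adjusted p = 0.077). Adjusted over the list alone, these lists had 0 higher and 0 lower genes for the proteasome, 5 and 3 for subtype identity, 5 and 2 for the retinoid response, 6 and 4 for the Notch pathway, 1 and 6 for endoplasmic reticulum stress, 0 and 4 for cholesterol synthesis, 1 and 3 for mesoderm, 0 and 3 for blood and endothelium, and 3 and 4 for REST targets. For glia, the retinoid response and REST targets the sign of the median, the mean or the test differed from the others. By fry, which does not compare a list with other genes, retinoid response (adjusted p = 4e-04), Wnt targets (0.0077) and Notch pathway (0.038) were higher on balance. Lower by fry were ventral neural tube (adjusted p = 0.00076), cholesterol synthesis (0.0045), REST targets (0.0046), blood and endothelium (0.012), mesoderm (0.023) and endoplasmic reticulum stress (0.023). The rest of these lists did not pass fry in 1 direction. By fry's mixed p-value, for change in either direction, neural crest (adjusted p = 5.6e-08), neuronal subtype identity (1.4e-06) and proliferation (5.9e-05) passed. So did huntingtin and partners (7.5e-05), proteasome (0.00016) and respiratory chain (0.0077), but not Hox genes (0.12) and glia (0.52).

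Htt itself fell in CAG150 at day 4 (152 ± 12.6 to 105 ± 9.7, log2 difference -0.48 ± 0.12, adjusted p = 0.016, lost without any of 4 arrays) and at day 6 (132 ± 22.1 to 65.1 ± 6.52, -0.86 ± 0.12, adjusted p = 0.00027). These values are from the brightest of 3 probe sets of Htt with enough signal, and neither of the others passed. They gave -0.46 ± 0.15 (adjusted p = 0.059) and -0.41 ± 0.28 (adjusted p = 0.38) at day 4, and 0.05 ± 0.15 and -0.39 ± 0.28 at day 6. Hprt was near the background in both lines, at 23.6 ± 2.55 in HM1 and 23.5 ± 6.47 in CAG150 at day 4 (adjusted p = 0.95) and at 24.4 ± 4.64 and 20.3 ± 4.4 at day 6 (adjusted p = 0.47). Genes of chromosomes 8 and 11 were shifted upward in CAG150 at both days, by a median log2 difference of 0.196 and 0.172 at day 4 and of 0.24 and 0.227 at day 6. The medians of the other 17 autosomes lay between -0.064 and 0.003. Of the genes named here with a rise, Rbfox3 and Otx1 are on chromosome 11.

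The next question was how the lines differed at day 6, later in differentiation. CAG150 cells then had more of the mRNAs of postmitotic neurons: Mapt, the microtubule protein tau, rose from 193 ± 44.3 in HM1 to 441 ± 1.35 in CAG150 (log2 difference 1.15 ± 0.12, n = 3 per group, adjusted p = 3e-05), and Tubb3 rose from 2060 ± 246 to 3090 ± 440 (0.58 ± 0.13, adjusted p = 0.0088). Mapt is on chromosome 11 and Tubb3 on chromosome 8. Zic1, a dorsal neural regulator, rose 6.15-fold, from 181 ± 15.8 to 1200 ± 202 (2.62 ± 0.13, adjusted p = 6.2e-08). The endoderm and pluripotency lists were lower. Among fibroblast and smooth muscle genes, a list that lost its call with an estimated correlation (adjusted p = 0.056), Acta2 fell 16.4-fold, from 2890 ± 221 to 162 ± 9.6 (-4.03 ± 0.11, adjusted p = 3.7e-10).

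At day 6, 2624 genes (21.4%) passed, 1243 higher and 1381 lower in CAG150. Chromosomes 8 and 11 held 231 and 320 of the higher genes. Without chromosomes 8, 11 and Y, 651 were higher and 1223 lower. With the arrays centred on their medians instead, 811 were higher and 1617 lower. With the mean of a gene's probe sets, 1279 were higher and 1152 lower. The groups did not overlap for 4735 genes, where chance gives 10%, and for 2583 of those that passed. A difference of at least 2-fold was seen for 80 higher and 222 lower genes. The largest rises were of Rspo2 (45.1 ± 5.82 to 808 ± 109, 13.4-fold) and its relative Rspo3 (8.95 ± 1.95 to 235 ± 34.3, 10-fold). Next came Msx3, a dorsal spinal cord regulator (6.43-fold), Zic1, Otx1 (4.34 ± 4.09 to 102 ± 30, 5.73-fold), Dmrta2 (5.05-fold), Slc17a6, a vesicular glutamate transporter (22.5 ± 11.3 to 172 ± 36.4, 4.95-fold), and Gsx1 (4.68-fold). With pseudocounts of 1 and 64 the log2 differences were 4.57 and 2.03 for Rspo3 and 4.48 and 1.27 for Otx1, so their folds depend on it. The largest falls were of Tagln (1760 ± 278 to 38.2 ± 7.39, 32.8-fold) and Acta2. They were followed by Anxa1 (412 ± 32.6 to 24.5 ± 3.32, 10.6-fold), Actc1, cardiac actin (8.56-fold), Vgll3 (8.51-fold), Anxa2 (7.43-fold), Cnn2 (7.17-fold) and Rln1 (1660 ± 117 to 229 ± 87.9, 7.1-fold).

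**Figure D1:**
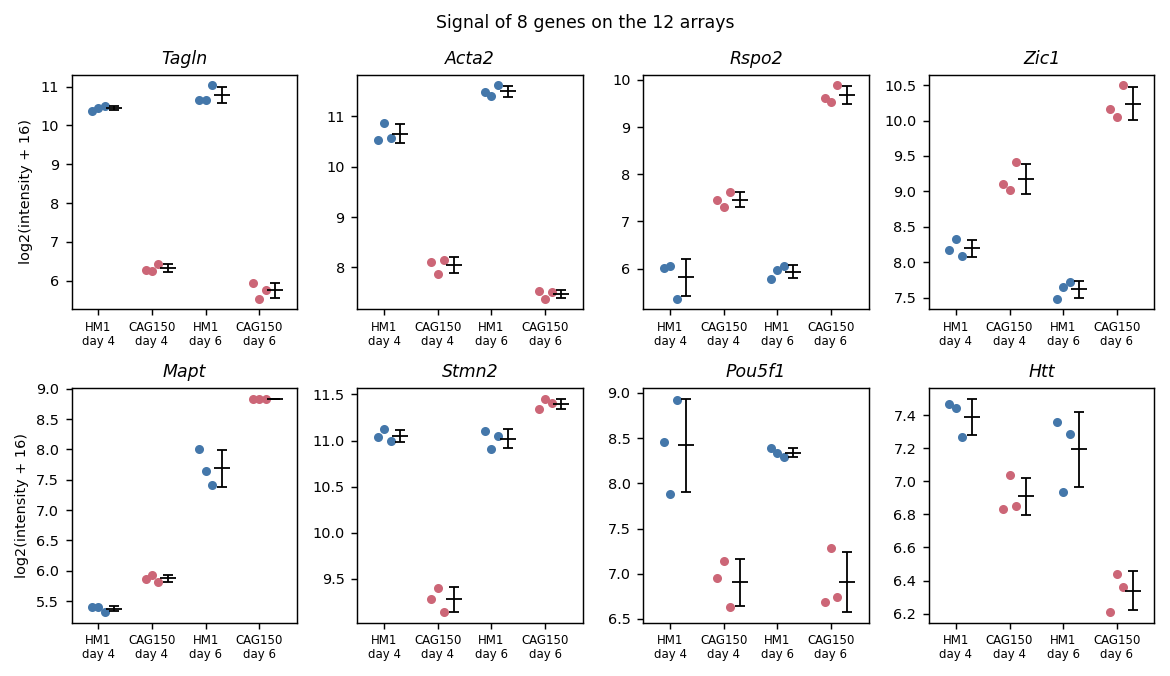
Signal of 8 genes on the 12 arrays, as log2(intensity + 16), by line and day. Each coloured point is an array, and the black line and bar are the mean and SD of its group. Tagln and Acta2 were lower and Zic1 was higher in every CAG150 array than in every HM1 array of the same day, and Stmn2 was lower in CAG150 at day 4 and not at day 6.

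The postmitotic neuron list rose at day 6: 22 of 30 genes were higher in CAG150 and 0 lower, against 26 and 0 adjusted over the list alone (median 0.43, adjusted p = 1.1e-11, and adjusted p = 0.038 with an estimated correlation). Map2, a dendrite microtubule protein, rose from 856 ± 74.4 to 1490 ± 50.6 and Stmn4 rose 1.67-fold. Of 18 proneural and neurogenic genes 8 rose and 1 fell, also adjusted over the list alone (median 0.26, adjusted p = 0.00064, and adjusted p = 0.12 with an estimated correlation). Neurog2, a switch of neuronal fate, rose from 76.6 ± 7.43 to 299 ± 62.6 and Myt1 rose 2.23-fold, while Neurog1 fell 1.84-fold. Of 15 neuronal subtype genes 5 rose and 1 fell, against 6 and 1 adjusted over the list alone (median 0.16, adjusted p = 0.048, and adjusted p = 0.12 with an estimated correlation). With the filter at the 60th percentile its median was -0.02 and it did not pass, nor did it without any of 5 arrays. Lhx9 rose 3.79-fold and Isl1, a regulator of motor and sensory neurons, fell from 351 ± 16 to 106 ± 14.5. Of 21 REST targets with Bdnf, a list that shares genes with the postmitotic neuron list, 7 rose and 3 fell, against 8 and 3 adjusted over the list alone (median 0.3, adjusted p = 0.013, and adjusted p = 0.057 with an estimated correlation). Calb1, a calcium-binding protein, rose 3.25-fold and Celf4 2.49-fold.

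Regional genes also differed at day 6. Of 9 forebrain and midbrain genes 4 rose and 0 fell, also adjusted over the list alone (median 0.41, adjusted p = 4.1e-05, and adjusted p = 0.057 with an estimated correlation). Otx2 rose 3.63-fold, and Emx2 rose from 8.85 ± 4.6 to 64.9 ± 16.3 (log2 difference 1.7, or 2.85 and 0.82 with pseudocounts of 1 and 64). Of 7 ventral neural tube genes 0 rose and 4 fell, against 1 and 4 adjusted over the list alone (median -0.79, adjusted p = 0.036, and adjusted p = 0.12 with an estimated correlation). Nkx6-1 fell 2.01-fold and Shh, the signal that patterns the ventral tube, fell from 62.3 ± 8.77 to 25 ± 8.63. Of 10 Wnt targets 5 rose and 1 fell, also adjusted over the list alone (median 0.37, adjusted p = 0.031, and adjusted p = 0.21 with an estimated correlation). Lef1 rose 2.63-fold and Ccnd1, cyclin D1, fell 1.76-fold.

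Lists of some other cell types were lower in CAG150 at day 6. The pluripotency list had 11 lower and 0 higher of 18, against 12 and 0 adjusted over the list alone (median -0.77, adjusted p = 4e-07, and adjusted p = 0.01 with an estimated correlation), with Pou5f1 2.7-fold lower (308 ± 10.4 to 106 ± 29.4) and Dppa5a 2.58-fold lower. Endoderm genes had 8 lower and 0 higher of 12, against 9 and 0 adjusted over the list alone (median -0.88, adjusted p = 4.1e-08, and adjusted p = 0.011 with an estimated correlation). Apoe fell 4.5-fold and Lrp2 3.32-fold. Fibroblast and smooth muscle genes had 4 lower and 0 higher of 9, also adjusted over the list alone (median -0.51, adjusted p = 2.3e-06, and adjusted p = 0.056 with an estimated correlation), and Cnn1 fell from 77.3 ± 12.2 to 2.5 ± 1.37 (log2 difference -2.33, or -4.56 and -1.08 with pseudocounts of 1 and 64). Mesoderm genes had 4 lower and 1 higher of 9, also adjusted over the list alone (median -0.27, adjusted p = 0.0056, and adjusted p = 0.057 with an estimated correlation), and Foxc1 fell from 106 ± 21.1 to 6.22 ± 1.23 (log2 difference -2.45, or -3.89 and -1.27 with pseudocounts of 1 and 64).

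Of 16 p53 targets and apoptosis genes 11 fell and 0 rose at day 6, also adjusted over the list alone (median -0.44, adjusted p = 0.00024). Cdkn1a fell from 1250 ± 118 to 515 ± 53.2 and Perp fell 2.22-fold. Of 19 endoplasmic reticulum stress genes 9 fell and 1 rose, against 12 and 2 adjusted over the list alone (median -0.26, adjusted p = 0.00038, and adjusted p = 0.12 with an estimated correlation), with Atf3, a stress-induced transcription factor, 2.25-fold lower. Of 17 heat shock genes 4 fell and 1 rose, also adjusted over the list alone (median -0.15, adjusted p = 0.025, and adjusted p = 0.29 with an estimated correlation). Hspb1 fell 3.65-fold and Chordc1 1.36-fold. Of 21 glycolysis and hypoxia genes 11 fell and 2 rose, against 14 and 3 adjusted over the list alone (median -0.36, adjusted p = 0.00024, and adjusted p = 0.21 with an estimated correlation), and Slc2a3, a neuronal glucose transporter, fell from 2220 ± 93.9 to 798 ± 47.8. The list of Hprt and sex chromosome genes fell (3 of 4 lower, 0 higher, also adjusted over the list alone, median -1.01, adjusted p = 0.0013, and adjusted p = 0.056 with an estimated correlation), with Eif2s3y 4.85-fold and Uty 2.53-fold lower.

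The lists that did not pass camera's test against all other genes at day 6 were neural progenitor (5 higher and 2 lower of 20, 8 and 2 adjusted over the list alone, adjusted p = 0.19), glia (1 and 0 of 6, adjusted p = 0.88), Hox genes (1 and 1 of 7, adjusted p = 0.75), retinoid response (2 and 5 of 14, adjusted p = 0.44), neural crest (5 and 3 of 12, adjusted p = 0.22), blood and endothelium (0 and 2 of 5, adjusted p = 0.33) and proliferation (1 and 2 of 23, adjusted p = 0.11). The others were proteasome (2 and 1 of 31, adjusted p = 0.77), cholesterol synthesis (2 and 0 of 19, adjusted p = 0.058), respiratory chain (0 and 1 of 33, adjusted p = 0.79), Notch pathway (6 and 2 of 18, adjusted p = 0.19), imprinted genes (2 and 6 of 20, adjusted p = 0.058) and huntingtin and partners (2 and 1 of 11, adjusted p = 0.75). Adjusted over the list alone, the counts were 2 and 7 for the retinoid response, 6 and 4 for neural crest, 1 and 0 for the proteasome, 0 and 0 for the respiratory chain, 7 and 3 for the Notch pathway and 4 and 6 for imprinted genes. For the proteasome the median and the test differed in sign. By fry, which does not compare a list with other genes, neural crest (adjusted p = 0.0019), neural progenitor (0.0032), cholesterol synthesis (0.0032) and Notch pathway (0.045) were higher on balance. Lower by fry were imprinted genes (adjusted p = 3.7e-05), blood and endothelium (0.033), proliferation (0.033) and retinoid response (0.034). The rest of these lists did not pass fry in 1 direction. By fry's mixed p-value huntingtin and partners (adjusted p = 5.1e-07), proteasome (3.8e-06), Hox genes (0.0011) and respiratory chain (0.035) passed, and glia (0.057) did not. Within the neural crest list, Tfap2b rose from 99.7 ± 25 to 515 ± 52.6 and Tfap2a 4.39-fold, and Ets1 fell 3.06-fold. Among imprinted genes Grb10 fell 6.03-fold and Cdkn1c 3.74-fold. Pax6, a neural progenitor regulator, fell from 1040 ± 37.3 to 781 ± 61 (adjusted p = 0.0068), and Nes was 421 ± 54.2 and 332 ± 19.4 (adjusted p = 0.12).

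**Figure D2:**
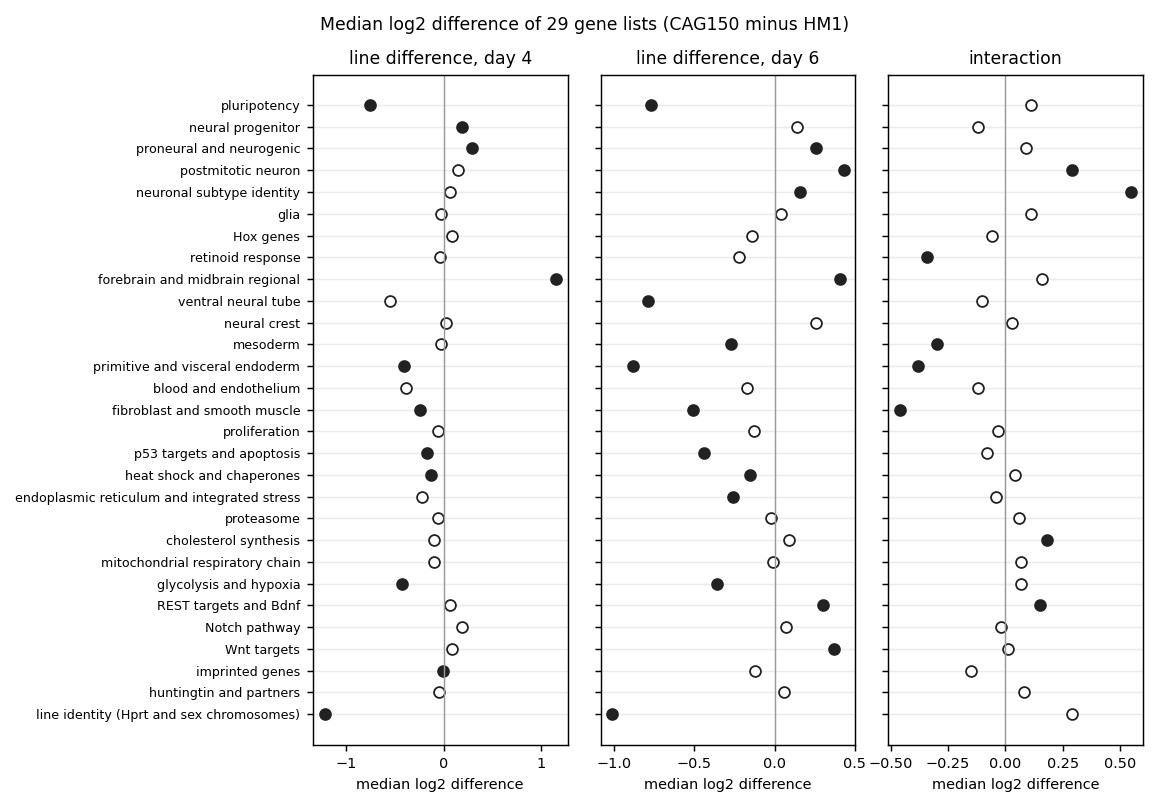
Median log2 difference of each of the 29 gene lists for the line difference at day 4, the line difference at day 6 and the line by day interaction. Filled points passed the list test at an adjusted p under 0.05 with the preset correlation, and open points did not. The postmitotic neuron list lies at 0.15 at day 4 and at 0.43 at day 6.

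The day comparison within HM1 asked what changed as the control line differentiated. Neuronal genes rose strongly from day 4 to day 6: Dcx, a microtubule protein of young neurons, rose 14.5-fold, from 40.6 ± 2.49 to 808 ± 67.8 (log2 difference 3.86 ± 0.09, n = 3 per group, adjusted p = 7.1e-11). Tubb3 rose 3.8-fold, Nes 2.39-fold and Pax6 3.53-fold, while Pou5f1 was 341 ± 124 and 308 ± 10.4 (adjusted p = 0.81). The Hox list rose, and Hoxb2 rose from 45 ± 11.8 to 603 ± 18.4 (3.36 ± 0.13, adjusted p = 2.3e-09), while En1, a midbrain and hindbrain regulator, fell from 101 ± 13.9 to 9.25 ± 1.9 (-2.21 ± 0.16, adjusted p = 5.9e-07).

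In HM1 4773 genes (38.9%) passed, 2500 higher and 2273 lower at day 6. With the arrays centred on their medians, 1750 were higher and 3085 lower, and the median of all genes was -0.109, so the direction of small changes depends on the scaling. With the mean of a gene's probe sets, 2406 were higher and 1900 lower. The groups did not overlap for 6024 genes, where chance gives 10%. The largest rises after Dcx were of the neurogenic genes Nhlh2 (12.6-fold) and Neurog1 (11.3-fold), Cartpt, a neuropeptide (10.4-fold), Hoxb2, Rufy3 (10.2-fold), Dner, a neuronal Notch ligand (10-fold), and Wnt7a (8.98-fold, with -0.15 by another of its probe sets). The largest falls were of Eras (7.27-fold), Tnfrsf19 (6.18-fold), Irs4 (4.92-fold), Tal2 (4.66-fold), En1, Gdf10 (3.99-fold), Fgfbp1 (3.91-fold) and H2-K1 (3.79-fold, with 0.02 by another of its probe sets). With pseudocounts of 1 and 64 the log2 differences were -3.33 and -1.17 for En1 and -3.24 and -1.21 for Tal2. Htt was 152 ± 12.6 at day 4 and 132 ± 22.1 at day 6 (-0.2 ± 0.12, adjusted p = 0.21), and Hprt did not pass (adjusted p = 0.92).

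Of 30 postmitotic neuron genes 28 rose in HM1, also adjusted over the list alone (median 1.82, adjusted p = 1.1e-23, and adjusted p = 0.015 with an estimated correlation), Nefm, a neurofilament, by 8.78-fold. Of 18 proneural genes 17 rose, also adjusted over the list alone (median 1.77, adjusted p = 1.9e-14), and Ebf3 rose 5.45-fold. Further lists that rose were neuronal subtype identity (9 of 15, median 0.85, adjusted p = 0.00014), Hox genes (5 of 7, median 1.05, adjusted p = 0.00047), retinoid response (8 of 14, median 0.67, adjusted p = 0.00014) and REST targets (14 of 21, median 0.52, adjusted p = 0.00055). Neural progenitor genes rose (14 of 20, adjusted p = 2.4e-05, and adjusted p = 0.051 with an estimated correlation), with Pou3f3 5.28-fold higher. The same held for neural crest (6 of 12, adjusted p = 0.015, and adjusted p = 0.092 with an estimated correlation), mesoderm (5 of 9, adjusted p = 0.015, and adjusted p = 0.088 with an estimated correlation), endoderm (8 of 12, adjusted p = 0.035, and adjusted p = 0.15 with an estimated correlation) and the Notch pathway (8 of 18, adjusted p = 0.015, and adjusted p = 0.25 with an estimated correlation).

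Cholesterol synthesis fell in HM1 (15 of 19 genes lower, also adjusted over the list alone, median -0.46, adjusted p = 5.7e-06), with Lss 2.09-fold lower. Proliferation fell (13 of 23, adjusted p = 2.4e-05, and adjusted p = 0.088 with an estimated correlation), with Ccne1, cyclin E1, 1.91-fold lower, and so did glycolysis (11 of 21, adjusted p = 0.00013, and adjusted p = 0.18 with an estimated correlation), with Slc2a3 2.92-fold lower. The other falls were of forebrain and midbrain genes (6 of 9, adjusted p = 0.003, and adjusted p = 0.13 with an estimated correlation), Wnt targets (4 of 10, adjusted p = 0.0012, and adjusted p = 0.088 with an estimated correlation), endoplasmic reticulum stress (8 of 19, adjusted p = 0.015, and adjusted p = 0.27 with an estimated correlation) and the proteasome (5 of 31, but 0 adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.43 with an estimated correlation). The pluripotency list did not pass (6 higher and 3 lower of 18, adjusted p = 0.52), with Dppa5a 2.04-fold higher and Lin28a 1.99-fold lower. Adjusted over the list alone, the genes higher and lower in HM1 at day 6 were 15 and 3 for neural progenitor, 9 and 1 for neuronal subtype, 5 and 0 for Hox, 9 and 1 for retinoid response, 14 and 3 for REST targets, 6 and 3 for neural crest, 6 and 0 for mesoderm, 8 and 2 for endoderm and 8 and 4 for Notch. They were 1 and 14 for proliferation, 0 and 11 for glycolysis, 1 and 6 for forebrain and midbrain, 0 and 5 for Wnt targets and 2 and 8 for endoplasmic reticulum stress. For glia, blood and endothelium, and p53 targets the signs of the median, the mean and the test were not alike.

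The same comparison in CAG150 asked what changed as the repeat line differentiated. The postmitotic neuron list rose here too. Tfap2b, a regulator of neural crest and dorsal interneurons, rose 18-fold, from 13.7 ± 4.27 to 515 ± 52.6 (4.17 ± 0.15, n = 3 per group, adjusted p = 1.7e-09). Dcx rose 12-fold, from 78.5 ± 7.01 to 1120 ± 41.3 (3.59 ± 0.09, adjusted p = 1.8e-10), Gap43, a growth cone protein, 10.4-fold and Tubb3 5-fold. En1 fell 9.64-fold, from 244 ± 36.8 to 11.2 ± 6.19 (-3.27 ± 0.16, adjusted p = 1.4e-08). Nes rose 2.49-fold and Pax6 2.32-fold, although another Pax6 probe set gave -0.02, and Pou5f1 was 105 ± 21 and 106 ± 29.4 (adjusted p = 0.99).

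In CAG150 5453 genes (44.4%) passed, 2760 higher and 2693 lower at day 6. The counts were 1974 and 3474 with the arrays centred on their medians, and 2611 and 2356 with the mean of a gene's probe sets. The groups did not overlap for 6754 genes, where chance gives 10%. The largest rises also included the long noncoding RNA C130071C03Rik (11.4-fold), Dner (10.3-fold), Nhlh2 (9.76-fold), Cartpt (8.77-fold) and Thsd7a (7.97-fold). The largest falls after En1 were of Eras (8.73-fold), Tnfrsf19 (7.21-fold), Wnt1 (6.47-fold), Fgf8, the midbrain-hindbrain organiser signal (97.4 ± 11.9 to 3.98 ± 4.96, 5.76-fold), Il17rd (5.59-fold), Slc38a4 (5.52-fold) and Tcfl5 (5.28-fold). With pseudocounts of 1 and 64 the log2 differences were -4.48 and -2.03 for En1, -4.26 and -1.91 for Eras and -4.77 and -1.25 for Fgf8. Htt fell from 105 ± 9.7 to 65.1 ± 6.52 in CAG150 (-0.57 ± 0.12, adjusted p = 0.0017), although its other probe sets gave 0.07 and 0.36. Hprt did not pass (adjusted p = 0.53).

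Of 30 postmitotic neuron genes 29 rose in CAG150, also adjusted over the list alone (median 2.13, adjusted p = 1.8e-25, and adjusted p = 0.0053 with an estimated correlation), Nefm by 7.85-fold. Of 18 proneural genes 17 rose, also adjusted over the list alone (median 1.64, adjusted p = 1.1e-13), with Ebf2 7.17-fold higher. Rises were also seen for neuronal subtype identity (13 of 15, median 0.97, adjusted p = 4.8e-07), with Slc17a6 6.08-fold higher, REST targets (18 of 21, median 0.87, adjusted p = 7.2e-07), with Chgb 6.07-fold higher, Hox genes (5 of 7, 1 lower, adjusted p = 0.0026) and the retinoid response (8 of 14, adjusted p = 0.0026). Neural progenitor genes (15 of 20, adjusted p = 7.5e-05, and adjusted p = 0.072 with an estimated correlation), neural crest genes (7 of 12, adjusted p = 0.004, and adjusted p = 0.064 with an estimated correlation) and the Notch pathway (9 of 18, adjusted p = 0.013, and adjusted p = 0.27 with an estimated correlation) rose. Proliferation fell (17 of 23, adjusted p = 2.8e-05, and adjusted p = 0.11 with an estimated correlation), with Ccne1 2.55-fold lower. Falls were further seen for cholesterol synthesis (9 of 19, adjusted p = 0.031, and adjusted p = 0.21 with an estimated correlation), glycolysis (11 of 21, adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation), endoplasmic reticulum stress (9 of 19, adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation) and Wnt targets (6 of 10, adjusted p = 0.007, and adjusted p = 0.15 with an estimated correlation). Slc2a3 fell 4.89-fold and Chac1, a gene of the integrated stress response, fell 4.23-fold. Members went the other way in the REST (2), retinoid (2), neural progenitor (1), neural crest (1), Notch (2), proliferation (1), cholesterol (2), glycolysis (2) and endoplasmic reticulum stress (2) lists. Adjusted over the list alone, 18 proliferation genes were lower and 1 higher and 10 cholesterol synthesis genes were lower and 2 higher, and the other lists given here kept their counts. For endoderm genes the mean and the median differed in sign.

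Averaged over both days, the line comparison asked how CAG150 and HM1 differed in the mean of their differences at day 4 and day 6. A large difference at a single day can pass it too. Rspo2 was 6.49-fold higher in CAG150 (log2 difference 2.7 ± 0.12, n = 6 arrays per line, adjusted p = 9e-09) and Tagln was 24-fold lower (-4.58 ± 0.09, adjusted p = 6.8e-12). Further rises were of Rspo3 (4.4-fold), Otx1 (3.7-fold), Gsx1 (3.67-fold), Zic1 (3.49-fold), Mab21l2 (3.49-fold), Tal2 (3.35-fold) and Dmrt3 (3.33-fold). The log2 differences with pseudocounts of 1 and 64 were 2.96 and 1.26 for Rspo3, 2.97 and 1.06 for Otx1, 2.92 and 1.07 for Gsx1 and 2.3 and 1.12 for Tal2. Further falls were of Acta2 (9.99-fold), Vgll3 (7.31-fold), Eif2s3y (6.96-fold), Anxa1 (6.65-fold), Anxa2 (6.38-fold), Krt8, a keratin of simple epithelia (6.09-fold), and Rln1 (5.88-fold). Pou5f1 fell 2.78-fold, Tubb3 rose 1.3-fold, Htt fell 1.59-fold, Nes fell 1.28-fold although its other probe sets gave 0.56 and 0.47, and Pax6 (adjusted p = 0.25) and Hprt (adjusted p = 0.54) did not pass.

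On average 3675 genes (29.9%) passed, 1859 higher and 1816 lower. For 2007 of them the groups did not overlap at day 4 nor at day 6, with the same direction at both. With the arrays centred on their medians 1182 were higher and 2411 lower. The counts were 1998 and 1487 with the mean of a gene's probe sets, and 1037 and 1665 without chromosomes 8, 11 and Y. Lists lower in CAG150 with both correlations were pluripotency (12 of 18 lower, adjusted p = 7.1e-09), endoderm (9 of 12, adjusted p = 8.5e-07) and p53 targets (11 of 16, adjusted p = 0.00016). Lists higher with the preset correlation and not with an estimated one were postmitotic neuron (18 higher and 3 lower of 30, 22 and 3 adjusted over the list alone, adjusted p = 4.5e-06, and adjusted p = 0.11 with an estimated correlation), proneural (9 of 18, adjusted p = 7.2e-05, and adjusted p = 0.11 with an estimated correlation), forebrain and midbrain (7 of 9, adjusted p = 1.2e-05, and adjusted p = 0.066 with an estimated correlation), neural progenitor (9 higher and 2 lower of 20, median 0.07, adjusted p = 0.02, and adjusted p = 0.21 with an estimated correlation) and Wnt targets (4 higher and 2 lower of 10, adjusted p = 0.035, and adjusted p = 0.21 with an estimated correlation). Neuronal subtype identity (adjusted p = 0.15) and REST targets (adjusted p = 0.33) did not pass. Another 8 lists fell with the preset correlation and not with an estimated one. These were glycolysis (15 lower and 1 higher of 21, adjusted p = 2.6e-06, and adjusted p = 0.14 with an estimated correlation), fibroblast and smooth muscle (5 of 9, adjusted p = 3.6e-05, and adjusted p = 0.1 with an estimated correlation), endoplasmic reticulum stress (11 of 19, adjusted p = 0.00084, and adjusted p = 0.15 with an estimated correlation) and heat shock (7 lower and 1 higher of 17, adjusted p = 0.0039, and adjusted p = 0.21 with an estimated correlation). They included imprinted genes (7 lower and 3 higher of 20, adjusted p = 0.02, and adjusted p = 0.15 with an estimated correlation), mesoderm (4 of 9, adjusted p = 0.023, and adjusted p = 0.11 with an estimated correlation), ventral neural tube (4 lower and 1 higher of 7, adjusted p = 0.027, and adjusted p = 0.11 with an estimated correlation) and Hprt with sex chromosome genes (3 of 4, adjusted p = 0.00084, and adjusted p = 0.066 with an estimated correlation). Adjusted over the list alone, 14 pluripotency genes were lower and 1 higher, 11 p53 targets lower and 1 higher, 12 endoplasmic reticulum stress genes lower and 1 higher, 15 glycolysis genes lower and 2 higher, 11 proneural genes higher and 0 lower, and 5 Wnt targets higher and 2 lower. For glia, Hox genes and cholesterol synthesis the signs of the median, the mean and the test were not alike.

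The interaction asked whether the change from day 4 to day 6 differed between the lines. Dbx1, a regulator of ventral and intermediate interneurons, rose from 233 ± 20.2 to 1950 ± 186 in HM1 and was 397 ± 52.3 and 426 ± 32.5 in CAG150 (log2 interaction -2.88 ± 0.16, n = 3 per group, adjusted p = 3.5e-06). Stmn2 was 2110 ± 101 and 2060 ± 143 in HM1 and rose from 607 ± 56.8 to 2690 ± 102 in CAG150 (2.15 ± 0.13, adjusted p = 3.6e-06). Lhx2, a forebrain regulator, fell from 213 ± 25.5 to 72 ± 6.54 in HM1 and rose from 89.5 ± 12.3 to 195 ± 12.6 in CAG150 (2.39 ± 0.16, adjusted p = 6.5e-06).

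The interaction passed for 443 genes (3.6%), 194 with a larger and 249 with a smaller day 6 minus day 4 difference in CAG150. The count was 270 without CAG150 day 6 replicate 3, 295 without CAG150 day 4 replicate 2, 295 without a filter and 269 with the replicate block nested in the line. The largest positive interactions besides Lhx2 and Stmn2 were of Ptf1a, a regulator of inhibitory neurons (2.44 ± 0.23), Cacna2d1, a calcium channel subunit (2.39 ± 0.17), Rspo3 (2.37 ± 0.15), Tfap2b (2.23 ± 0.21), Msx3 (2.13 ± 0.21) and Calb2 (2.11 ± 0.37). The largest negative interactions besides Dbx1 were of Hbegf, a growth factor (-2.06 ± 0.17), Tecrl (-2.03 ± 0.19), Neurog1 (-1.93 ± 0.23), Wnt7a (-1.85 ± 0.26), Apcdd1 (-1.83 ± 0.31), Foxc1 (-1.69 ± 0.26) and Tox2 (-1.65 ± 0.25). The values of dim genes depended on the pseudocount, and other pseudocounts are given for those with a group mean below the filter intensity. With 64 instead of 16 the interaction was 1.16 for Ptf1a, 1.53 for Rspo3, -1.01 for Tecrl and -0.91 for Foxc1. With 1 it was 3.23 for Rspo3 and -2.69 for Foxc1, while Ptf1a and Tecrl did not pass the filter. Pax6 rose less in CAG150 than in HM1 (-0.6 ± 0.13, adjusted p = 0.021, lost without any of 4 arrays). The interaction did not pass for Tubb3 (adjusted p = 0.32), Pou5f1 (adjusted p = 0.94), Nes (adjusted p = 0.93), Htt (-0.37 ± 0.17, adjusted p = 0.29) and Hprt (adjusted p = 0.8).

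No list kept its interaction with an estimated correlation. Postmitotic neuron genes had 7 positive and 0 negative interactions of 30, against 10 and 2 adjusted over the list alone (median 0.29, adjusted p = 2.4e-06, and adjusted p = 0.097 with an estimated correlation), with Gng3 at 1.47 ± 0.12. Neuronal subtype genes had 4 and 2 of 15, against 5 and 2 adjusted over the list alone (median 0.55, adjusted p = 0.021, and adjusted p = 0.097 with an estimated correlation), with Slc17a6 at 1.63 ± 0.29 and Isl1 at -1.57 ± 0.18. With a pseudocount of 64 Slc17a6 was at 1.22, and with 1 it was at 0.89 and did not pass. REST targets had 3 and 0 of 21, against 5 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.0018, and adjusted p = 0.094 with an estimated correlation), with Calb1 at 1.55 ± 0.21 (1.94 and 0.93 with pseudocounts of 1 and 64). Cholesterol synthesis had 1 and 0 of 19, against 4 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.00043, and adjusted p = 0.094 with an estimated correlation), with Fdft1, squalene synthase, at 0.55 ± 0.12, a call lost without any of 7 arrays. Negative shifts were of the retinoid response (1 and 5 of 14, median -0.34, adjusted p = 0.022, and adjusted p = 0.097 with an estimated correlation), with Crabp1 at -0.82 ± 0.15, and mesoderm (1 and 3 of 9, median -0.3, adjusted p = 0.019, and adjusted p = 0.097 with an estimated correlation), with Foxc1 and Isl1. They were also of endoderm (0 and 3 of 12, median -0.38, adjusted p = 0.0014, and adjusted p = 0.094 with an estimated correlation), with Col4a1 at -1.03 ± 0.13, and of fibroblast and smooth muscle genes (0 and 3 of 9, median -0.46, adjusted p = 0.0018, and adjusted p = 0.18 with an estimated correlation), with Acta2 at -1.42 ± 0.16. Adjusted over the list alone, the positive and negative interactions were 1 and 6 for the retinoid response, 1 and 4 for mesoderm, 0 and 5 for endoderm and 0 and 5 for fibroblast and smooth muscle genes. For imprinted genes and for blood and endothelium the signs of the median, the mean and the test were not alike.

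The line differences at both days were compared across genes, which are not independent replicates. Of the genes that passed, 465 were higher in CAG150 at both days, where 97.9 are given by independent lists, 569 were lower at both days, where 109.4 are given, and 49 went opposite ways. The log2 line differences of the 12280 genes had a Pearson's r of 0.62 and a Spearman's rho of 0.51 between the days. The day differences had r of 0.82 and rho of 0.78 between the lines, with 1874 genes higher at day 6 in both lines (561.9 given by independent lists), 1698 lower in both (498.5) and 49 opposite. The arrays compared were not shared in either case.

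**Figure D3:**
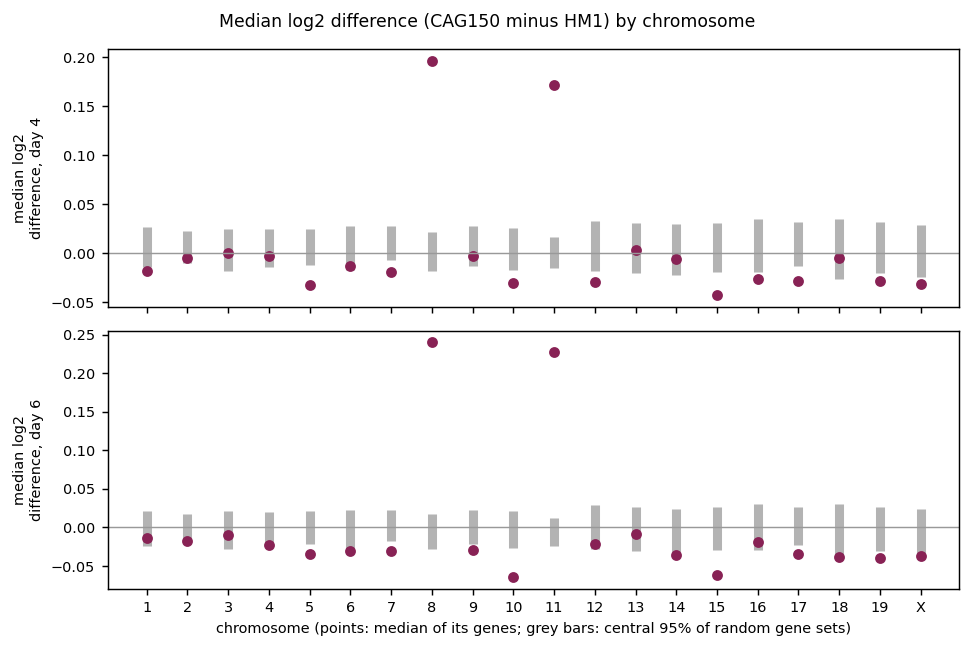
Median log2 difference between CAG150 and HM1 of the tested genes of each chromosome at day 4 and day 6. Points are chromosomes, and grey bars are the central 95% of medians of 10000 random gene sets of the same size matched on signal. Chromosomes 8 and 11 lie at 0.196 and 0.172 at day 4 and at 0.24 and 0.227 at day 6, above the bars. Some other chromosomes lie below their bars, such as 10 and 15 (-0.03 and -0.043 at day 4, -0.064 and -0.061 at day 6). The random sets were drawn from all tested genes, those of chromosomes 8 and 11 included, which raises the bars.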

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

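The tests of the expanded repeat, of the share of neural cells and of the other Htt probe sets were chosen only after the results were seen, and so were the comparison by chromosome itself and the fit without genes of chromosomes 8, 11 and Y behind the dosage test.

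Genes of chromosomes 8 and 11 were higher in CAG150 than in HM1 at both days, on every CAG150 array relative to every HM1 array of the same day. Array scaling that depends on signal is argued against by the excess over the other autosomes, which was at least 0.195 under quantile normalization. There the medians of the other autosomes had an SD of at most 0.0161. Quantile normalization changes values by signal alone, whatever the chromosome, so it was a weak test of a shift on these chromosomes. The excess was at least 0.19 under median centring, which moves all genes of an array alike and so tests nothing here. An extra copy of both chromosomes in the CAG150 cells is a candidate explanation: with each chromosome divided into 4 parts by gene order, 16 of 16 medians over both chromosomes and days lay above the central 95% of matched random gene sets. With the genes divided into 3 sets by signal the median folds were between 1.07 and 1.22, below that of an added copy in every cell, and whether only part of the cells carry it or the array compresses folds was not tested. The expanded repeat and any other difference between the lines cannot be told apart, since there was 1 line of each kind.

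Postmitotic neuron genes were higher in CAG150 at day 6. The list's adjusted p was 2.6e-13 under quantile normalization, which argues against array scaling as the cause. It was 2.1e-12 under median centring, which moves all genes of an array alike and so tests nothing here. Direct dosage of the list's members on chromosomes 8 and 11 is argued against by an adjusted p of 3.7e-13 for the 27 genes on other chromosomes. An effect of an extra copy on genes of other chromosomes was not tested. These p-values are camera's with the preset correlation. With the deposited scaling and an estimated correlation the list's adjusted p was 0.038. The neuron list's median lay above that of the progenitor list by 0.3 (two-sided permutation test across 30 and 20 genes, p = 4e-05). Genes are not independent replicates, and the lists were compared after the neuron list had passed and the progenitor list had not. A larger share of all neural cells would raise both lists alike only if both were equally particular to neural cells. That was not tested, so such a larger share stays open. Faster maturation or a larger share of neurons in CAG150 may also account for the rise of the neuron list, and these were not separated. The pluripotency (median -0.77) and endoderm (-0.88) lists were lower at the same day, so a smaller share of other cells stays open beside them, all as hypotheses found and tested on the same data. The endoderm list stands here only for its 12 tested members of 20, without Afp and Ttr, which lay below the filter.

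Htt signal was lower in CAG150. At day 4, 1 of the 2 other Htt probe sets with enough signal also fell by limma's test before adjustment (-0.46 ± 0.15), though not after it (adjusted p = 0.059), and the other gave -0.41 ± 0.28 (adjusted p = 0.38), so whether the drop is a property of 1 probe set cannot be told apart from a lower transcript level. At day 6, 0 of these 2 fell by the same test before adjustment, with differences of -0.39 ± 0.28 and 0.05 ± 0.15, and the second is far from the -0.86 of the brightest probe set. One probe set's own behaviour, such as the transcript end it reads, may therefore contribute at day 6, and a lower level of part of the transcripts stays open.

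The change from day 4 to day 6 differed between the lines for 443 genes, by the interaction test, and for 270 without CAG150 day 6 replicate 3, 295 without CAG150 day 4 replicate 2, 295 without a filter and 269 with the replicate block nested in the line. Of 100 splits of the samples 8 gave as many, the real one included, and the highest of the others gave 6777. That split exchanged the days in 1 line and so turned the day difference into the interaction, and without it the highest was 2437, while the median of the others was 0. The count of 6777 thus points to the structure of the samples. The days were shuffled within each line. A split that exchanged unequal numbers of arrays in the lines therefore carried part of the day difference into the interaction. Such splits do not measure chance for the interaction. What the other splits with as many genes exchanged was not examined, and the splits do not decide whether chance is excluded.

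Relative to other genes, 8 lists shifted in the interaction with the preset correlation and 0 with an estimated one (adjusted p between 0.094 and 0.18), with a median of 0.29 for postmitotic neuron, 0.55 for neuronal subtype, 0.18 for cholesterol synthesis, 0.15 for REST targets, -0.34 for retinoid response, -0.3 for mesoderm, -0.38 for endoderm and -0.46 for fibroblast and smooth muscle genes. Single genes with a positive interaction were Ptf1a (2.44), Cacna2d1 (2.39), Lhx2 (2.39), Rspo3 (2.37), Tfap2b (2.23), Stmn2 (2.15), Msx3 (2.13), Calb2 (2.11), Slc17a6 (1.63), Calb1 (1.55), Gng3 (1.47) and Fdft1 (0.55). Those with a negative interaction were Dbx1 (-2.88), Hbegf (-2.06), Tecrl (-2.03), Neurog1 (-1.93), Wnt7a (-1.85), Apcdd1 (-1.83), Foxc1 (-1.69), Tox2 (-1.65), Isl1 (-1.57), Acta2 (-1.42), Col4a1 (-1.03), Crabp1 (-0.82) and Pax6 (-0.6).

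For the other comparisons the real split was set against other splits of the same samples, all 10 for a comparison of 6 arrays and 100 drawn for the average. In the average over both days 1 of 100 splits gave as many genes, the real one with 3675, and the highest other gave 672. This argues against a chance assignment of these arrays to the lines. Such splits cannot exclude chance differences between cultures or lines. The samples are not described as separate cultures, and there was 1 line of each kind. The 10 splits of 6 arrays are too few for a share under 0.05, and 1 of 10 gave as many in each case: 1940 genes at day 4 (highest other 1), 2624 at day 6 (highest other 0), 4773 in HM1 (highest other 1) and 5453 in CAG150 (highest other 0).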

How the results depend on the processing

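The fit without genes of chromosomes 8, 11 and Y was the only alternative chosen after the data were seen. It gave 1446 genes at day 4, 1874 at day 6, 2702 for the average and 381 for the interaction. Among the gene values named in the text, 9 reversed with another probe set of the same gene and 2 with the mean of probe sets, and 0 did in any other setting, while another 32 of 181 and 4 of 213 lost their call. Over all genes the naming rule allows, in all 6 comparisons, 69 of 1452 values reversed with another probe set and 5 of 1542 with the mean, and leaving out an array ended the call of 682 of 18864. With an estimated correlation 62 of 174 list results lost their call, and with fry 33 gained one. The replicate numbers gave no pairing: deviations of same-number samples correlated across genes by -0.133 to 0.122. Signal over background limits dim genes.

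At an adjusted p under 0.01 the counts were 897 at day 4, 1407 at day 6, 3123 in HM1, 2210 for the average and 162 for the interaction, fewer by construction. With a difference of at least 2-fold as well as an adjusted p under 0.05 they were 218, 302, 617, 807 (CAG150), 207 (average) and 147 (interaction). The interaction count was 295 without a filter and 269 with the replicate block nested in the line. The neuron list at day 4 passed with median centring (0.08, adjusted p = 0.049) and without a filter (0.15, adjusted p = 0.032), and over all alternatives other than leaving out arrays the adjusted p ranged up to 0.44. The correlation of the line effects was 0.545 without a filter, 0.66 at the 60th percentile, 0.577 with a pseudocount of 1 and 0.644 with 64, and that of the day effects 0.766, 0.846, 0.778 and 0.838. The neuronal subtype list at day 6 reversed at the 60th percentile (-0.02, adjusted p = 0.88, the highest over its alternatives). Other probe sets reversed Sparc at day 4 (0.32), Htt at day 6 (0.05), Wnt7a (-0.15) and H2-K1 (0.02) in HM1, Pax6 (-0.02) and Htt (0.07 and 0.36) in CAG150 and Nes in the average (0.56 and 0.47), and the mean of probe sets reversed Htt in CAG150 (0.03) and Nes in the average (0.23). The cause was not tested.

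Leaving out each array gave 1361 to 1921 genes at day 4, 1867 to 2645 at day 6, 3903 to 4774 in HM1, 4651 to 5524 in CAG150 and 3166 to 3461 for the average. The interaction gave 270 (without CAG150 day 6 replicate 3) to 362, and 295 without CAG150 day 4 replicate 2. The neuron list's median was 0.14 to 0.21 at day 4, where it passed without CAG150 day 4 replicate 3 (adjusted p = 0.018, and up to 0.15 without others), and 0.39 to 0.46 at day 6 (adjusted p = 4e-12 to 2.8e-10). Of the genes named, leaving out an array ended the call of Htt at day 4 (-0.44 without HM1 day 4 replicate 1 or CAG150 day 4 replicate 1, -0.46 without HM1 day 4 replicate 2 and -0.45 without CAG150 day 4 replicate 3, adjusted p between 0.052 and 0.057). It also ended the interaction of Pax6 (adjusted p up to 0.058 without any of 4 arrays) and of Fdft1 (up to 0.063 without any of 7), and the day 6 difference of Rbfox3 without any of 4. Of the list results 24 of 2088 lost their call, among them neuronal subtype identity at day 6 without any of 5 arrays (adjusted p up to 0.078) and imprinted genes at day 4 without any of 6. The correlations were 0.601 to 0.616 and 0.807 to 0.816.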

Other observations

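The counts of probe sets without a single gene symbol, given last, come from a further fit. None of the other values below was tested beyond the comparisons already described, so no test of them was chosen after a result was seen.

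Genes of the Y chromosome were low in CAG150. Eif2s3y, a translation factor subunit, was 331 ± 20.2 in HM1 and 19 ± 5.75 in CAG150 at day 4, and 185 ± 19.6 and 25.7 ± 6.15 at day 6. Uty, a histone demethylase homologue, was 81.7 ± 9.18 and 7.45 ± 1.83 at day 4, and 62.2 ± 18.6 and 14.3 ± 2.54 at day 6. Both differences passed at both days (limma, adjusted p between 2e-08 and 5.3e-05 over the genes tested).

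Among neural crest genes Pax3 and Ets1 moved apart, and the imprinted genes Grb10 and Phlda2 were both lower in CAG150. Grb10 was 1630 ± 111 in HM1 and 344 ± 80.2 in CAG150 at day 4, and 1700 ± 104 and 268 ± 12.1 at day 6, although it lies on chromosome 11. Phlda2, a growth regulator, was 62 ± 12.9 and 22.5 ± 4.9 at day 4, and 44.4 ± 8.69 and 10.3 ± 2.77 at day 6. Pax3, a regulator of the dorsal neural tube and crest, was 132 ± 35.6 and 409 ± 28.5 at day 4, and 382 ± 49.3 and 974 ± 142 at day 6. Ets1 was 110 ± 13.7 and 30.7 ± 9.72 at day 4, and 126 ± 18.9 and 30.2 ± 3.43 at day 6.

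Control probe sets read RNA quality on each array. The ratio of the 3' to the 5' Gapdh probe set was 0.826 ± 0.011 in HM1 and 0.813 ± 0.023 in CAG150 at day 4, and 0.77 ± 0.009 and 0.78 ± 0.032 at day 6 (mean ± SD, n = 3 per group). The actin ratio was 1.666 ± 0.247 and 1.504 ± 0.045 at day 4, and 1.592 ± 0.234 and 1.428 ± 0.054 at day 6. Probe sets with none or several gene symbols here were counted in a fit of all probe sets with enough signal, with p-values adjusted over all of these. The counts are therefore not directly comparable with those of the 12280 genes. Of 3940 such probe sets with enough signal, 265 passed for the line difference at day 4 and 432 at day 6. For the day difference 760 passed in HM1 and 981 in CAG150, with 736 for the average and 29 for the interaction.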
